A study of Homo sapiens with 13 samples.

How the data were processed

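Poly-A RNA of 2 ovarian carcinoma lines was measured in 13 libraries, 9 of SKOV3 and 4 of OVCAR3. Per the labels' protocols, RNA was extracted with TRIzol, captured on poly-T beads and copied with random hexamers. The authors deposited whole-number read counts per gene, not normalized, in 1 table per line, and these were used as deposited. Tools named in the submitters' processing notes are FastQC, STAR 2.7.9a and Subread, with the genome builds GRCh38, hg38 and GRCm38; the annotation release and the strand setting of the counting are not given in the sources used here. Gene identifiers are human, and 58264 of 58279 genes shared with GENCODE 29 overlap its GRCh38 positions. The tables list 62703 genes, of which 62625 have a symbol in the name table, and 1 record split over 3 lines (ANK2) was rejoined.

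Genes that share reads with near-identical copies, such as SAA1 and SAA2, HLA genes, AKR1C1 and AKR1C2, IFITM genes, PSG1, SPANXB1 and ribosomal protein genes, are uncertain. So are overlapping and antisense genes, since the use of strand is not stated.

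Groups came from the labels; the column read as OVCAR3 control replicate 2 has a letter in its name that no label explains. Each line was fitted on its own with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), using TMM scaling, filterByExpr with a minimum count of 10 and a quasi-likelihood test, with all groups of a line in 1 fit. P-values were adjusted by Benjamini-Hochberg over the genes tested in each of 4 comparisons, with a threshold of 0.05. This left 16735 genes in SKOV3 (biological coefficient of variation 0.0734, 6 residual degrees of freedom) and 18359 in OVCAR3 (0.124, 2 residual degrees of freedom). Fold changes used a prior count of 0.125, and standard errors are the absolute log2 fold change over the root of F. For genes at 0 counts in a group the fold is a lower bound from 3 counts over the group. Ratios for 1 to 3 counts have a 95% counting interval.

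The gene lists, the naming rule and the first set of alternatives were chosen before the data were examined. The text names RSF1 in every comparison. It also names the 8 largest rises and 8 largest falls among genes with adjusted p under 0.05, a mean log2 CPM of at least 2 and groups that do not overlap, without pseudogene, antisense, clone or bare identifier names. Of each list past its threshold, up to 2 risen and 2 fallen members with the smallest adjusted p are named, and of other lists only members past the threshold, smallest first. Some genes that the rule takes are not reported here. Genes outside this rule are said to be chosen after their values were seen. The 31 lists were: RSF and ISWI remodelling partners, Polycomb subunits and H2A deubiquitinases, HOX cluster genes, Developmental regulators known as polycomb targets, Replication-dependent histone genes, S-phase and E2F targets, G2/M and mitosis, p53 target genes, BCL2 family and caspases, NF-kappaB and inflammatory targets, Interferon-stimulated genes, Antigen presentation, Mesenchymal and EMT genes, Epithelial adhesion and keratin genes, Collagens and integrins, YAP and TGF-beta targets, Immediate early and AP-1 genes, MAPK feedback genes, ER stress and ATF4 targets, Hypoxia and glycolysis, Cholesterol synthesis, NRF2 targets, Ribosome biogenesis and MYC targets, Cytosolic ribosomal proteins, Nuclear-encoded respiratory chain, Mitochondrially encoded genes, Homologous recombination and Fanconi genes, Ovarian carcinoma and Muellerian markers, Immune cell markers, Fibroblast markers, Endothelial markers. They were tested with camera at a preset correlation of 0.01, adjusted over the lists with at least 3 tested genes, and again with an estimated correlation and with fry, which does not compare a list with other genes.

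Correlation between comparisons that share controls was set beside 100 simulations of unchanged groups. Arm medians used arms with at least 20 genes and 1000 permutations of genes over arms. The fits were tested on simulated data with 200 changed genes. In RSF1 against control in SKOV3 (15263 genes) they recovered 80.6%, 94.0% and 100% of genes changed by folds of 1.5, 2 and 4, and in OVCAR3 (17662 genes) 17.9%, 77.6% and 93.9%. Unchanged genes made up 6.15% and 3.82% of calls. Alternatives were other scalings, DESeq2 1.42.0, limma-voom, other count filters, a fold threshold of 1.5, the replicate number as a block, and each replicate left out.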

Results

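RNA was sequenced from 13 libraries of 2 human ovarian carcinoma cell lines. SKOV3 is a line from ascites known for an amplified ERBB2 gene, and OVCAR3 is a line from the ascites of a serous carcinoma. SKOV3 cells carried a control vector, RSF1, or RSF1delUAB, each in 3 libraries. RSF1 is a histone chaperone that forms the RSF remodelling complex with the ATPase SMARCA5 and binds ubiquitinated histone H2A, a mark laid down by Polycomb complexes, through its UAB region. RSF1delUAB lacks that region. OVCAR3 cells expressed a scrambled peptide or a peptide of the UAB region, each in 2 libraries, after 6 days with 2000 ng/mL doxycycline. The deposited values were read counts per gene, with total counts of 15194678 to 18748009 per SKOV3 library and 18160558 to 24026993 per OVCAR3 library.

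Libraries of one group resembled each other more than those of different groups. In SKOV3 the correlation of log2 CPM, counts scaled to the library total adjusted by TMM, was 0.987 to 0.992 within groups and 0.900 to 0.964 between them. In OVCAR3 it was 0.985 to 0.987 within groups and 0.963 to 0.970 between them. Every pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 2.28 to 16.3. The labels do not say whether replicates were separate cultures, so all p-values measure the spread between these samples, which may be technical. Levels below are TMM-scaled CPM as mean ± SD, with n = 3 libraries per SKOV3 group and n = 2 per OVCAR3 group. Counting intervals and lower bounds of folds cover counting error alone.

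RSF1 (ENSG00000048649, chromosome 11, 77660009 to 77820869 on GRCh38) was read first, as a check of the labels. Its level in SKOV3 was 44.0 ± 3.08 CPM with control vector, 719 ± 77.0 CPM with RSF1 and 488 ± 25.6 CPM with RSF1delUAB. The log2 fold change against control was 4.03 for RSF1 (adjusted p = 1.96e-18) and 3.47 for RSF1delUAB (adjusted p = 1.09e-17). The 3 RSF1 libraries were at 631, 775 and 749.8 CPM, and the 3 RSF1delUAB libraries at 459, 496 and 509 CPM. RSF1 was thus 0.56 log2 units higher in RSF1 than in RSF1delUAB libraries (adjusted p = 5.07e-06). A test against a fold of 1.5 could not pass here, since the estimate itself lies below that fold. It does not show that the levels were equal. In OVCAR3 the gene stood at 636 ± 101 CPM with the scrambled peptide and 687 ± 142 CPM with the UAB peptide, a log2 fold change of 0.11 that did not pass the test (adjusted p = 0.724). The groups overlapped, at 564 and 707 CPM with the scrambled peptide and 787 and 586 CPM with the UAB peptide. Without UAB replicate 1 the log2 fold change was -0.112, and without UAB replicate 2 it was 0.311. RSF1 therefore does not check the OVCAR3 labels or the expression of the peptide. Counts per gene cannot tell construct reads from endogenous ones, nor full-length from deleted RSF1.

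**Figure D1:**
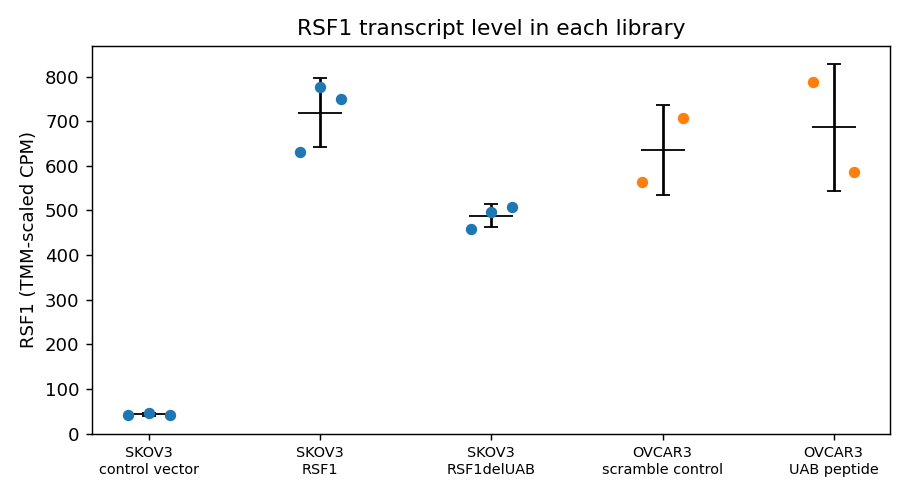
RSF1 level (TMM-scaled CPM, linear axis from 0) in each of the 13 libraries by group; points are libraries and bars are mean ± SD. All 6 construct libraries of SKOV3 lie at or above 459 CPM and the 3 control libraries at or below 47.5 CPM.

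The first comparison asked what RSF1 changes in SKOV3, a line with a low level of the gene. Cells given RSF1 had many transcripts that the control lacked. SLCO2B1, an organic anion transporter, reached 77.1 ± 10.5 CPM against 0 counts in the control, at least 1176-fold higher. SLC43A3, a purine transporter, reached 72.4 ± 2.74 CPM, at least 1102-fold higher, and the adhesion gene TENM4 34.2 ± 12.7 CPM, at least 522-fold higher. SAA1, an acute-phase protein, stood at 118 ± 19.7 CPM against 0.0442 ± 0.0766 CPM, a ratio of 2694 (95% counting interval 745 to 22247). In the other direction TMPRSS15, which encodes enteropeptidase, went from 34.6 ± 5.09 CPM to 0 counts, at least 542-fold lower. SERPINB5, the serpin maspin, went from 113 ± 7.96 to 0.855 ± 0.345 CPM (log2 fold change -7.03).

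The other genes with the largest rises were ARRDC4, LRATD1, CERNA2 and ARMCX3, all at 0 counts in the control and at least 498-, 426-, 370.2- and 306-fold higher. The other largest falls were LINC02864 (at least 228-fold lower), COL4A5 (control over RSF1 ratio 839.8 (95% counting interval 232 to 6940.0)), SPANXB1 (-8.10), RAB34 (-7.58), XYLT1 (-6.68) and HSPB8 (-6.39), the last 4 as log2 fold changes. In all, 5747 of 16735 tested genes were higher and 5514 lower, and 2718 and 1715 of these changed at least 2-fold.

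Of the 31 gene lists fixed beforehand, 30 could be tested in SKOV3 and 7 differed from other genes, 5 upwards and 2 downwards. Counts adjusted over the list alone are given where they differ from the printed counts over all genes. Of fibroblast markers, 8 of 9 tested members rose, 0 fell and 1 did not pass (median log2 fold change 3.01, adjusted p = 3.02e-08), among them the matrix proteins FBLN1 at 135 ± 5.47 against 5.10 ± 0.362 CPM and MFAP5 at a log2 fold change of 3.01. FBLN1 lies on 22q, an arm whose median was 0.91 log2 units higher. The immune cell marker CD4 stood at 0.576 ± 0.0746 CPM with RSF1 and 0.759 ± 0.463 CPM with RSF1delUAB against 0.0436 ± 0.0378 CPM in the control, ratios of 13.1 (95% counting interval 3.30 to 114) and 17.4 (4.52 to 149). Of mesenchymal and EMT genes, 15 of 23 tested members rose, 5 fell and 3 did not pass; 16 rose and 5 fell adjusted over the list alone (median log2 fold change 0.92, adjusted p = 4.62e-08). The gelatinase MMP2 went from 8.15 ± 0.102 to 206 ± 13.2 CPM and the matrix protein TGFBI from 27.2 ± 2.57 to 298 ± 5.36 CPM, while the calcium-binding protein S100A4 (-2.04) and the transcription factor SNAI2 (-1.06) fell. Both lists also passed with an estimated correlation, at adjusted p = 0.0107 and 0.0107.

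NF-kappaB and inflammatory targets rose as a list: 17 of 24 tested members rose, 5 fell and 2 did not pass (median log2 fold change 0.87, adjusted p = 1.51e-07, and adjusted p = 0.0630 with an estimated correlation). The mitochondrial superoxide dismutase SOD2 went from 291 ± 5.18 to 2054 ± 55.7 CPM and the chemokine CCL20 from 0.658 ± 0.0743 to 32.2 ± 2.85 CPM, while the cytokine IL1A fell from 181 ± 6.73 to 88.1 ± 2.79 CPM. Of epithelial adhesion and keratin genes, 13 of 21 tested members rose, 3 fell and 5 did not pass (median log2 fold change 0.84, adjusted p = 0.00141, and adjusted p = 0.0959 with an estimated correlation); LCN2, a secreted siderophore-binding protein, rose by 7.58 log2 units and the desmosomal gene DSP fell by 0.99. Of antigen presentation genes, 13 of 17 tested members rose, 2 fell and 2 did not pass (median log2 fold change 0.43, adjusted p = 0.0342, and adjusted p = 0.137 with an estimated correlation), with HLA-E at 1.25 and HLA-C at 0.93. This list's call ended with an offset per chromosome arm (adjusted p = 0.0985).

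MAPK feedback genes fell as a list: 3 of 18 tested members rose, 13 fell and 2 did not pass (median log2 fold change -1.07, adjusted p = 0.000186, and adjusted p = 0.0959 with an estimated correlation). The receptor kinase EPHA2 went from 873 ± 29.8 to 177 ± 8.87 CPM and the phosphatase DUSP4 from 118 ± 5.90 to 22.1 ± 1.21 CPM, whereas the EGFR ligand EREG rose by 3.76 log2 units. Of cholesterol synthesis genes, 6 of 24 tested members rose, 13 fell and 5 did not pass (median log2 fold change -0.51, adjusted p = 0.0342, and adjusted p = 0.126 with an estimated correlation); the demethylase MSMO1 fell by 1.62 log2 units. MSMO1 lies on 4q, an arm whose median was -0.78.

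The remaining lists held many changed members and did not pass the test against other genes. Some lay near the threshold: leaving out any 1 of the 6 libraries gave 9 or 10 lists past it in place of 7, the YAP and TGF-beta list among them each time. The histone list passed without control replicate 1 or 2, the NRF2 list without any 1 control or RSF1 replicate 1, and the ribosomal protein list without control replicate 3 or RSF1 replicate 2 or 3. Among chromatin lists, 3 rose and 6 fell of 12 RSF and ISWI remodelling partners, 7 rose and 20 fell of 40 Polycomb subunits and H2A deubiquitinases (adjusted p = 0.0695), 8 rose and 4 fell of 23 HOX cluster genes and 10 rose and 6 fell of 26 developmental regulators. The Polycomb list included CBX6 at 1.87 and the deubiquitinase USP16 at -1.07. Of histone genes, 1 rose and 8 fell of 9 (adjusted p = 0.0512). For cell cycle lists, 15 rose and 12 fell of 34 S-phase and E2F targets and 12 rose and 10 fell of 30 G2/M genes. For stress and death, 8 rose and 12 fell of 23 p53 targets, with GDF15 at 4.58 and CDKN1A at -2.14, 6 rose and 9 fell of 22 BCL2 family members and caspases, and 9 rose and 8 fell of 26 ER stress and ATF4 targets.

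Of signalling lists, 13 rose and 11 fell of 31 interferon-stimulated genes, 7 rose and 7 fell of 19 immediate early genes and 12 rose and 6 fell of 22 YAP and TGF-beta targets (12 rose and 7 fell adjusted over the list alone; adjusted p = 0.0512). Of metabolic lists, 6 rose and 12 fell of 24 hypoxia and glycolysis genes, 6 rose and 11 fell of 19 NRF2 targets (adjusted p = 0.0545), 7 rose and 14 fell of 32 nuclear-encoded and 7 rose and 0 fell of 13 mitochondrially encoded respiratory chain genes. Mitochondrial genes took 3.51 to 3.59 percent of counts in control, 4.12 to 4.33 percent in RSF1 and 4.39 to 5.21 percent in RSF1delUAB libraries. For growth, 3 rose and 12 fell of 26 ribosome biogenesis genes and 27 rose and 7 fell of 43 ribosomal proteins (adjusted p = 0.0512). Of collagens and integrins 18 rose and 12 fell of 30, of homologous recombination genes 9 rose and 10 fell of 31, of ovarian carcinoma markers 3 rose and 6 fell of 12, and of endothelial markers 1 rose and 2 fell of 5. Median, mean and test differed in sign for 9 of these lists, namely HOX, developmental, G2/M, p53, immediate early, hypoxia, homologous recombination, ovarian and endothelial.

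The second comparison asked what RSF1 without its UAB region changes. ARRDC4, an alpha-arrestin, reached 114 ± 4.25 CPM against 0 counts in the control, at least 1736-fold higher. LRATD1, CERNA2, SLCO2B1, SLC43A3, ARMCX3, TENM4 and the glucose transporter SLC2A10 were also at 0 counts in the control, and were at least 723-, 428-, 392-, 365-, 360.5-, 314- and 271-fold higher. The basement membrane collagen COL4A5, TMPRSS15, LINC02864 and the fibrillin FBN2 were at 0 counts in RSF1delUAB cells, at least 624-, 604-, 254- and 227-fold lower. SERPINB5 fell from 113 ± 7.96 to 0.111 ± 0.0884 CPM, as did the calcium pump ATP2B2 (-7.30) and FAM83A (-6.46), and the control over RSF1delUAB ratio of WNT10A was 256 (95% counting interval 87.1 to 1243). In all, 5774 of 16735 genes were higher and 5376 lower, of which 2628 and 1654 changed at least 2-fold.

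Of the 30 lists, 9 differed from other genes, 4 upwards and 5 downwards. Of fibroblast markers, 7 of 9 tested members rose, 0 fell and 2 did not pass; 8 rose and 0 fell adjusted over the list alone (median log2 fold change 3.52, adjusted p = 1.74e-12). The proteoglycan LUM went from 0.591 ± 0.132 to 80.5 ± 5.12 CPM and FBLN1 from 5.10 ± 0.362 to 165 ± 5.64 CPM. Of antigen presentation genes, 14 of 17 tested members rose, 1 fell and 2 did not pass (median log2 fold change 0.71, adjusted p = 4.13e-06), with HLA-C at 1.92 and HLA-E at 1.87. These 2 lists also passed with an estimated correlation, at adjusted p = 0.00695 and 0.0386. Of mesenchymal genes, 13 of 23 tested members rose, 8 fell and 2 did not pass; 14 rose and 8 fell adjusted over the list alone (median log2 fold change 0.90, adjusted p = 0.000428, and adjusted p = 0.0510 with an estimated correlation), with TGFBI at 4.26 and MMP2 at 4.32. Of epithelial genes, 15 of 21 tested members rose, 4 fell and 2 did not pass (median log2 fold change 0.88, adjusted p = 9.18e-05, and adjusted p = 0.0541 with an estimated correlation), led by CD24 at 2.90 and LCN2 at 5.40.

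NF-kappaB targets fell in RSF1delUAB cells: 6 of 24 tested members rose, 15 fell and 3 did not pass (median log2 fold change -0.76, adjusted p = 0.000336, and adjusted p = 0.115 with an estimated correlation). The interleukins IL1A and IL1B went from 181 ± 6.73 to 3.47 ± 0.466 CPM and from 56.7 ± 0.873 to 2.42 ± 0.718 CPM, while SOD2 (0.93) and the adhesion molecule ICAM1 (2.76) rose. Of histone genes, 1 of 9 tested members rose, 8 fell and 0 did not pass (median log2 fold change -1.99, adjusted p = 0.0119, and adjusted p = 0.101 with an estimated correlation), with H2BC12 at -2.83 and H1-2 at -2.03. Of MAPK feedback genes, 2 of 18 tested members rose, 13 fell and 3 did not pass (median log2 fold change -0.49, adjusted p = 0.000336, and adjusted p = 0.0900 with an estimated correlation), with EPHA2 at -2.76 and DUSP4 at -2.26. Of NRF2 targets, 3 of 19 tested members rose, 11 fell and 5 did not pass (median log2 fold change -0.31, adjusted p = 0.00137, and adjusted p = 0.264 with an estimated correlation); the aldo-keto reductases AKR1C2 and AKR1C1 fell by 4.14 and 2.25, and the heme oxygenase HMOX1 rose by 1.58 log2 units. Of ribosome biogenesis genes, 3 of 26 tested members rose, 21 fell and 2 did not pass (median log2 fold change -0.50, adjusted p = 0.000336, and adjusted p = 0.0674 with an estimated correlation), with RRP9 at -1.91 and the polyamine enzyme ODC1 at -1.61, against a rise of the nucleolar methyltransferase FBL (1.22).

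Outside those lists, the coagulation initiator F3, counted among YAP and TGF-beta targets, fell from 982 ± 18.4 to 61.6 ± 1.37 CPM, and the immediate early factor EGR1 rose from 13.9 ± 1.14 to 161 ± 3.20 CPM. Polycomb subunits and H2A deubiquitinases did not differ from other genes (9 rose and 21 fell of 40; adjusted p = 0.343), nor did RSF and ISWI partners (3 rose and 5 fell of 12; adjusted p = 0.681). Median, mean and test differed in sign for the HOX, p53, YAP, immediate early and endothelial lists, which did not pass.

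Fold changes of both constructs against the same 3 control libraries were then set side by side. Across 16735 genes, which are not independent replicates, Pearson r was 0.860. Simulated unchanged groups against these controls gave a mean of 0.517 (0.467 to 0.554 in 100 simulations). The covariance was 1.96 against a simulated 0.0515, a difference of 1.91. Both constructs shared the sign for 83.9% of genes, against 66.9% in the simulations. They shared 4598 higher genes (1983 for independent lists) and 4253 lower genes (1771), and 128 and 205 genes were called in opposite directions. The simulations already hold the noise of the shared controls at the fitted spread. With 3 controls, no split leaves 2 libraries on each side. A difference of the control libraries from both construct groups, beyond that noise, may still make up part of the excess.

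Whole chromosome arms differed between control and construct libraries. The median log2 fold change of 22q was 0.91 with RSF1 and 0.90 with RSF1delUAB, that of 19q 0.63 and 0.45, and that of 14q 0.57 and 0.51. In the other direction 4q stood at -0.78 and -0.79, and 13q at -0.69 and -0.72. Above, the arm was marked for FBLN1 and MSMO1 only. HMOX1 and CBX6 also lie on 22q, and other named genes may lie on shifted arms. Across 41 arms the medians of both comparisons correlated (Pearson r 0.964, Spearman rho 0.939). Both share the control libraries, and unchanged groups were not simulated for arms, so part of this correlation may come from the shared controls. The SD of the arm medians was 0.379 with RSF1, above all of 1000 permutations of genes over arms (largest 0.0966, permutation p = 0.001, the smallest they can give). With an offset per arm and library, 5 named genes changed sign in RSF1 against control: HMGXB4 (0.51 before), SMARCA5 (-0.69), DLGAP5 (0.54), RPL15 (-0.57) and ATP5F1B (-0.43).

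**Figure D2:**
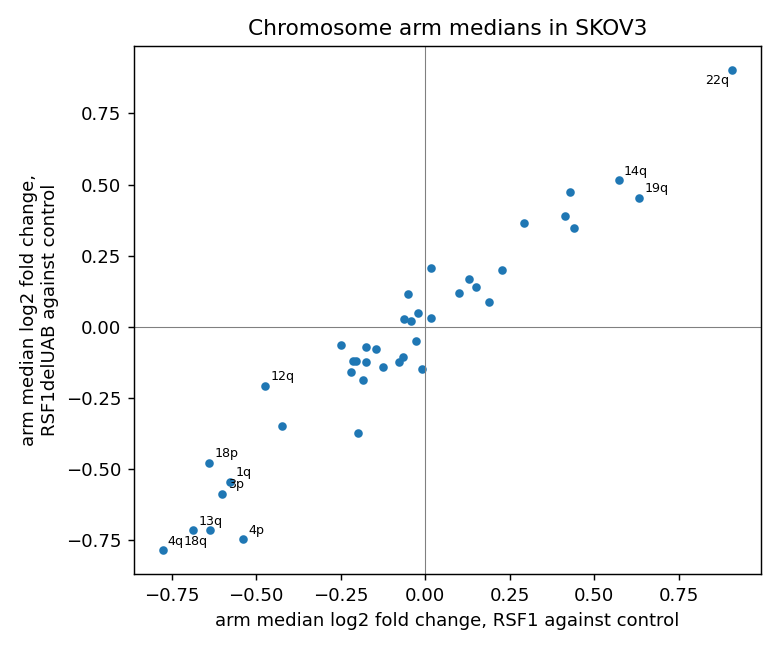
Median log2 fold change of the expressed genes of each of 41 chromosome arms in SKOV3, RSF1 against control (horizontal) and RSF1delUAB against control (vertical); points are arms, and grey lines mark 0. The arms lie along a common diagonal from 4q (-0.78, -0.79) to 22q (0.91, 0.90).

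The third comparison set RSF1 against RSF1delUAB, which differ in the UAB region and in level. Control libraries shared its filter, scaling and estimate of spread; with the 2 groups alone 16102 genes were tested, 2850 higher and 2984 lower. POSTN, the matrix protein periostin, was at 72.6 ± 4.24 CPM with RSF1 and at 0 counts with RSF1delUAB, at least 1266-fold higher. The cytokine IL1A stood at 88.1 ± 2.79 CPM with RSF1, 3.47 ± 0.466 with RSF1delUAB and 181 ± 6.73 with control vector. CCL20 was at 32.2 ± 2.85, 0.390 ± 0.294 and 0.658 ± 0.0743 CPM in the same order, and the EGFR ligand EREG was 6.80 log2 units higher with RSF1 than with RSF1delUAB. Lower with RSF1 were the metalloproteinase MMP7 (23.9 ± 4.49 against 248 ± 4.32 CPM), the AP-1 subunit FOS (4.35 ± 0.947 against 44.1 ± 1.06 CPM) and the small GTPase RAB34 (0.147 ± 0.131 against 47.3 ± 0.769 CPM).

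The other largest rises were LCP1 (5.95), PSG1 (5.44) and DAW1 (4.98) as log2 fold changes, and FBN2, at least 78.7-fold higher. The other largest falls were HSPB8 (-5.27), HMCN1 (-3.83), MAL (-3.32), TMEM59L (-3.31) and the lipoxygenase ALOX5 (-3.26). In all, 3088 of 16735 genes were higher and 3380 lower, of which 780 and 700 changed at least 2-fold. Of the 3088 higher genes, 902 were above control with both constructs, 647 above control with RSF1 and without a call for RSF1delUAB, 701 below control with both, 583 below control with RSF1delUAB and without a call for RSF1, 128 above with RSF1 and below with RSF1delUAB, and 127 without a call in either. Of the 3380 lower genes, 898, 604 and 205 were above control with RSF1delUAB, the last 205 with a fall below control for RSF1. A further 868 were below control with both, 669 below control with RSF1 and without a call for RSF1delUAB, and 136 without a call in either.

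NF-kappaB and inflammatory targets separated the constructs more than any other of the 30 lists by adjusted p: 21 of 24 tested members rose, 0 fell and 3 did not pass (median log2 fold change 2.06, adjusted p = 1.92e-68, and adjusted p = 0.000725 with an estimated correlation). SOD2 was at 2054 ± 55.7 CPM with RSF1, 556 ± 15.5 with RSF1delUAB and 291 ± 5.18 with control. Among members chosen after their values were seen, the chemokine CXCL8 differed by 4.19, the cytokine IL6 by 4.47 and the NF-kappaB inhibitor gene NFKBIA by 1.05 log2 units. CXCL8 was higher than control with RSF1 (2.43) and lower with RSF1delUAB (-1.77).

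Of YAP and TGF-beta targets, 14 of 22 tested members rose, 2 fell and 6 did not pass (median log2 fold change 0.73, adjusted p = 2.10e-08, and adjusted p = 0.00585 with an estimated correlation), with F3 at 1.82 and the activin subunit INHBA at 2.05. F3 was at 218 CPM with RSF1, 61.6 with RSF1delUAB and 981 with control, so both constructs lay below control. INHBA was at 77.5, 18.7 and 2.73 CPM in the same order. Of mesenchymal genes, 11 of 23 tested members rose, 7 fell and 5 did not pass (median log2 fold change 0.17, mean 0.69, adjusted p = 0.000505, and 0.0322 with an estimated correlation); the matrix protein SPARC fell by 2.80. Cholesterol synthesis genes fell: 0 of 24 tested members rose, 18 fell and 6 did not pass; 0 rose and 21 fell adjusted over the list alone (median log2 fold change -0.67, adjusted p = 1.02e-11, and adjusted p = 0.00311 with an estimated correlation), with the desaturase SC5D at -1.12 and the SREBP regulator INSIG1 at -1.11. Of antigen presentation genes, 0 of 17 tested members rose, 10 fell and 7 did not pass (median log2 fold change -0.37, adjusted p = 2.61e-05, and adjusted p = 0.0301 with an estimated correlation); HLA-B, a class I heavy chain, had a log2 fold change of -1.64 and HLA-C of -0.99. Of fibroblast markers, 0 of 9 tested members rose, 6 fell and 3 did not pass (median log2 fold change -0.51, adjusted p = 0.00224, and adjusted p = 0.0479 with an estimated correlation), with LUM at -1.92 and COL1A2 at -1.22. Of ribosome biogenesis genes, 19 of 26 tested members rose, 0 fell and 7 did not pass; 22 rose and 0 fell adjusted over the list alone (median log2 fold change 0.31, adjusted p = 8.89e-05, and adjusted p = 0.0403 with an estimated correlation), with the spermidine synthase SRM at 0.68.

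Proliferation and ribosomal protein lists were also higher with RSF1 than with RSF1delUAB, by small amounts. Of S-phase and E2F targets, 21 of 34 tested members rose, 1 fell and 12 did not pass (median log2 fold change 0.30, adjusted p = 0.000153, and adjusted p = 0.115 with an estimated correlation), with the clamp loader RFC3 at 1.17 and the histone mRNA-binding protein SLBP at 0.64. Of G2/M genes, 19 of 30 tested members rose, 1 fell and 10 did not pass; 19 rose and 2 fell adjusted over the list alone (median log2 fold change 0.22, adjusted p = 0.00278, and adjusted p = 0.136 with an estimated correlation), with the mitotic genes CDC20 and TTK at 0.51 and 0.53. Of ribosomal protein genes, 24 of 43 tested members rose, 3 fell and 16 did not pass; 26 rose and 3 fell adjusted over the list alone (median log2 fold change 0.26, adjusted p = 0.000799, and adjusted p = 0.728 with an estimated correlation). RSF1 replicate 1 had relatively more counts in short genes (difference of median log2 deviation between the longest and the shortest genes, by quartile, -0.238, against 0.133 and 0.110 in replicates 2 and 3). Without it 3374 genes were higher and 3707 lower in this comparison.

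Of ER stress and ATF4 targets, 16 of 26 tested members rose, 4 fell and 6 did not pass; 17 rose and 4 fell adjusted over the list alone (median log2 fold change 0.29, adjusted p = 0.0307, and adjusted p = 0.376 with an estimated correlation), and without RSF1 replicate 1 the adjusted p was 0.0595. Of NRF2 targets, 9 of 19 tested members rose, 6 fell and 4 did not pass; 10 rose and 6 fell adjusted over the list alone (median log2 fold change 0.21, adjusted p = 0.0403, and adjusted p = 0.404 with an estimated correlation), and without RSF1delUAB replicate 3 the adjusted p was 0.0628, and with an offset per chromosome arm it was 0.0786. Chromatin lists did not differ from other genes: 2 rose and 4 fell of 12 RSF and ISWI partners (3 rose and 5 fell adjusted over the list alone), 5 rose and 14 fell of 40 Polycomb subunits and H2A deubiquitinases (5 rose and 15 fell adjusted over the list alone) and 2 rose and 9 fell of 23 HOX genes (2 rose and 10 fell adjusted over the list alone). Immediate early genes went both ways (8 rose and 5 fell of 19), with EGR1 at -2.12 and JUN at 1.02. Median, mean and test differed in sign for the RSF partner, HOX, developmental, BCL2, immediate early and MAPK lists, which did not pass.

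Of ovarian carcinoma markers, 3 of 12 tested members rose, 7 fell and 2 did not pass (median log2 fold change -0.31, adjusted p = 0.000714, and adjusted p = 0.0409 with an estimated correlation). The receptor kinase ERBB2 (ENSG00000141736, chromosome 17, 39687914 to 39730426) was at 2493 ± 339.6 CPM with RSF1, 7567 ± 254 with RSF1delUAB and 8429.9 ± 358 with control. It fell against RSF1delUAB by 1.60 (adjusted p = 8.78e-13) and did not differ past the threshold between RSF1delUAB and control (-0.16, adjusted p = 0.0619). Of the 44 other tested genes within 1 Mb, 43 were lower with RSF1 than with RSF1delUAB, 37 of them past the threshold (median -0.64). Neighbours picked after their values were seen include PPP1R1B (-2.15), MIEN1 (-1.59), GRB7 (-1.29) and STARD3 (-0.93). Against control the 44 neighbours had a median of -0.23 with RSF1 (23 called lower, 7 higher) and of 0.50 with RSF1delUAB (6 lower, 25 higher). PPP1R1B was at -3.98 with RSF1 and -1.83 with RSF1delUAB against control, MIEN1 at -1.87 and -0.28, GRB7 at -0.23 and 1.05, and STARD3 at -0.71 and 0.22. The folate receptor FOLR1 was also lower (-2.94) and the surface protein MSLN higher (1.25).

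Longer stretches of chromosomes also differed between the constructs. The SD of arm medians was 0.0982, against a largest of 0.0386 in 1000 permutations of genes over arms (permutation p = 0.001, the smallest they can give), with 12q at -0.27, 8q at -0.24 and 17q at -0.24. In segments of 10 Mb looked at after the arm values were seen, chromosome 17 from 20 to 50 Mb had medians of -0.47, -0.36 and -0.48, with 41 of 45, 73 of 83 and 130 of 144 genes lower with RSF1. Chromosome 12 from 100 to 140 Mb had medians of -0.48, -0.47, -0.43 and -0.42. Some lower members of the Polycomb and HOX lists, looked up after their values were seen, lie in these stretches. They are PCGF2 (-0.38), EZH1, HOXB5 and HOXB6 on chromosome 17 and KDM2B on chromosome 12. Their falls cannot be told apart from those of the stretches.

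**Figure D3:**
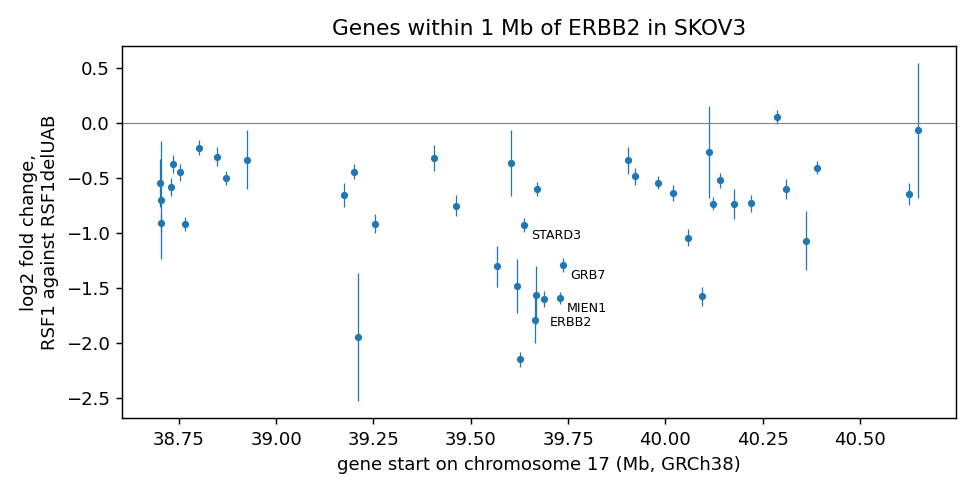
Log2 fold change of RSF1 against RSF1delUAB for ERBB2 and the 44 other tested genes within 1 Mb on chromosome 17 (start position in Mb, GRCh38); points are genes and bars are standard errors. All but 1 of the 44 neighbours lie below 0, with a median of -0.64.

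The fourth comparison asked what a peptide of the UAB region changes in OVCAR3, whose RSF1 level was 636 ± 101 CPM. The chemokine CXCL1 had a log2 fold change of -2.68, CXCL8 went from 33.7 ± 1.75 to 4.04 ± 1.00 CPM and CXCL2 from 44.1 ± 1.49 to 6.81 ± 0.140 CPM. IDO1, which degrades tryptophan, went from 16.7 ± 0.208 to 1.16 ± 0.0214 CPM. The transcription factor LHX1 rose from 0.495 ± 0.0949 to 34.4 ± 3.01 CPM, and WSCD2 from 0.0432 ± 0.0611 to 29.9 ± 3.14 CPM, a ratio of 698 (95% counting interval 193 to 5772).

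The other largest rises, as log2 fold changes, were the receptor phosphatase PTPRM (6.09), the GABA receptor subunit GABRA2 (4.32), DOC2B (4.08), the adrenergic receptor ADRA2A (3.84), VIT (3.78) and BMP3 (3.45). The other largest falls were the calcium channel subunits CACNG7 (-4.26) and CACNG6 (-3.21), NLRP2 (-3.70), RRAD (-3.60), MFAP5 (-3.03) and the cholesterol hydroxylase CH25H (-2.99). In all, 1001 of 18359 genes were higher and 1003 lower, of which 468 and 460 changed at least 2-fold. With 2 libraries per group, 633 were higher and 707 lower without control replicate 1, and 1194 and 1045 without control replicate 2. Replicates within each group also differed in their trend with gene length (-0.138 and 0.138 in the controls, 0.157 and -0.157 with the peptide, as longest minus shortest genes by quartile; with 2 replicates the deviations mirror each other by construction). With a gene-length offset 1296 genes were higher and 1345 lower.

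Of 31 lists tested, 8 differed from other genes, all downwards. None of these calls held with an estimated correlation (smallest adjusted p = 0.305), and fry called none (smallest adjusted p = 0.0622). Of NF-kappaB targets, 0 of 25 tested members rose, 17 fell and 8 did not pass; 1 rose and 21 fell adjusted over the list alone (median log2 fold change -1.39, adjusted p = 5.67e-34, and adjusted p = 0.305 with an estimated correlation). Of interferon-stimulated genes, 0 of 33 tested members rose, 14 fell and 19 did not pass; 0 rose and 20 fell adjusted over the list alone (median log2 fold change -0.58, adjusted p = 1.08e-11, and adjusted p = 0.409 with an estimated correlation), with IFI27 at -2.34 and the ubiquitin-like ISG15 at -1.18. Of antigen presentation genes, 0 of 19 tested members rose, 9 fell and 10 did not pass; 0 rose and 12 fell adjusted over the list alone (median log2 fold change -0.42, adjusted p = 3.78e-09, and adjusted p = 0.409 with an estimated correlation), with the immunoproteasome subunit PSMB9 at -2.23 and HLA-DRA at -2.81. Of immediate early and AP-1 genes, 0 of 19 tested members rose, 13 fell and 6 did not pass (median log2 fold change -0.76, adjusted p = 6.17e-14, and adjusted p = 0.409 with an estimated correlation), with FOS at -1.80 and IER3 at -1.26.

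Of epithelial genes, 0 of 25 tested members rose, 5 fell and 20 did not pass (median log2 fold change -0.14, adjusted p = 0.0145, and adjusted p = 0.409 with an estimated correlation), with LCN2 going from 38.1 ± 1.20 to 5.16 ± 1.19 CPM and the keratin KRT19 falling by 0.90. Of NRF2 targets, 0 of 19 tested members rose, 5 fell and 14 did not pass; 0 rose and 7 fell adjusted over the list alone (median log2 fold change -0.24, adjusted p = 0.00712, and adjusted p = 0.409 with an estimated correlation), with the ferritin chain FTH1 and the glutathione synthesis subunit GCLM both at -0.79. Of MAPK feedback genes, 3 of 17 tested members rose, 6 fell and 8 did not pass; 3 rose and 8 fell adjusted over the list alone (median log2 fold change -0.40, adjusted p = 0.0185, and adjusted p = 0.409 with an estimated correlation), with DUSP5 at -1.72, PHLDA1 at -1.61 and DUSP4 at 2.10. Without UAB replicate 2 this list's adjusted p was 0.0810. Of fibroblast markers, 1 of 8 tested members rose, 3 fell and 4 did not pass; 1 rose and 4 fell adjusted over the list alone (median log2 fold change -0.51, adjusted p = 0.0324, and adjusted p = 0.600 with an estimated correlation), with COL1A2 at -1.37. That call ended without control replicate 1 (adjusted p = 0.703), control replicate 2 (0.182) or UAB replicate 2 (0.224), and 5 of its 14 genes are in another list too.

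Chromosome arms differed in OVCAR3 too. The SD of arm medians was 0.107, against a largest of 0.0397 in 1000 permutations of genes over arms (permutation p = 0.001, the smallest they can give). The median of 16p was -0.41, with 8.28% of its 314 expressed genes above 0, and that of 10p 0.29. In segments of 10 Mb looked at after the arm values were seen, chromosome 16 from 0 to 40 Mb had medians of -0.40, -0.43, -0.37 and -0.44. Mitochondrial genes took 7.23 to 7.48 percent of counts in control and 6.22 to 6.57 percent in UAB peptide libraries; of mitochondrially encoded genes 0 rose and 1 fell of 13 (0 rose and 5 fell adjusted over the list alone; adjusted p = 0.0616).

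Lists that did not differ still held single changed genes. Of ovarian carcinoma markers 7 rose and 5 fell of 20 (10 rose and 7 fell adjusted over the list alone), with the WNT coreceptor LGR5 at 2.81, the transcription factor WT1 at 2.20 and the hyaluronan receptor CD44 at -2.84. Of developmental regulators 6 rose and 7 fell of 32 (11 rose and 9 fell adjusted over the list alone), with BMP7 at 1.49 and BMP4 at -1.58. Of p53 targets 2 rose and 2 fell of 23 (4 rose and 3 fell adjusted over the list alone), with TP53INP1 at 2.09 and the death receptor FAS at -1.87. Of collagens and integrins 5 rose and 6 fell of 29 (6 rose and 6 fell adjusted over the list alone), with the integrin ITGB5 at 1.90 and COL8A1 at -2.15. Of immune cell markers 0 rose and 1 fell of 4, the fall being that of the monocyte receptor CD14 (-2.64). Of Polycomb subunits and H2A deubiquitinases 2 rose and 1 fell of 40, and of RSF and ISWI partners 1 rose and 0 fell of 12 (adjusted over the list alone, 3 rose and 2 fell, and 3 rose and 0 fell). For 5 lists, developmental, BCL2, mesenchymal, collagens and hypoxia, median, mean and test differed in sign.

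The last comparison asked whether genes that differ between RSF1 and RSF1delUAB in SKOV3 respond to the UAB peptide in OVCAR3, in tables that share no library. Of 25 NF-kappaB targets tested in OVCAR3, 23 were also tested in SKOV3; 21 of these had opposite signs in RSF1 against RSF1delUAB and in UAB peptide against scrambled peptide, and 14 were called higher in the first and lower in the second. Across 15004 genes tested in both lines, 262 were called higher with RSF1 and lower with the peptide, against 148 for independent lists (two-sided Fisher's exact test, p = 4.19e-23). The reverse pair held 296 genes against 163 (two-sided Fisher's exact test, p = 5.21e-29). Genes called in the same direction numbered 146 higher against 142 and 204 lower against 171 (Fisher's exact test, p = 0.703 and 0.00395). On 16p, an arm with a median of -0.41 in OVCAR3 and 0.08 in RSF1 against RSF1delUAB, lay 32 of the 262 genes; without that arm, a choice made after seeing the data, 230 genes stood against 132 (two-sided Fisher's exact test, p = 1.97e-19) and 295 of the reverse pair against 165 (p = 6.47e-28). Without it the same direction held 146 higher genes against 141 and 197 lower against 155 (Fisher's exact test, p = 0.599 and 0.000134). Genes are not independent, so these p-values overstate the evidence. Fold changes of all 15004 genes were nearly uncorrelated (Pearson r -0.0746, Spearman rho -0.0952).

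As whole sets, genes called in SKOV3 did not shift past the threshold in OVCAR3. The 2736 tested genes higher with RSF1 than with RSF1delUAB had a median log2 fold change of -0.06 (adjusted p = 0.0788 over 4 sets), and the 3148 lower genes 0.05 (adjusted p = 0.366). Sets from RSF1 against control were at 0.02 and -0.00481 (both adjusted p = 0.627). The 517 genes at least 2-fold higher with RSF1 than with RSF1delUAB had a median of -0.136 and passed at the preset correlation (adjusted p = 0.00775), but not with an estimated one (adjusted p = 0.0675 with an estimated correlation). The full set had a median of -0.0934 without UAB replicate 2 and -0.0864 without control replicate 2. It had -0.0492 without UAB replicate 1 and -0.0259 without control replicate 1, so its shift varied with the library left out. Its camera adjusted p was 0.0643 with an offset per arm, 0.113 with the replicate number as a block and 0.552 with an estimated correlation.

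**Figure D4:**
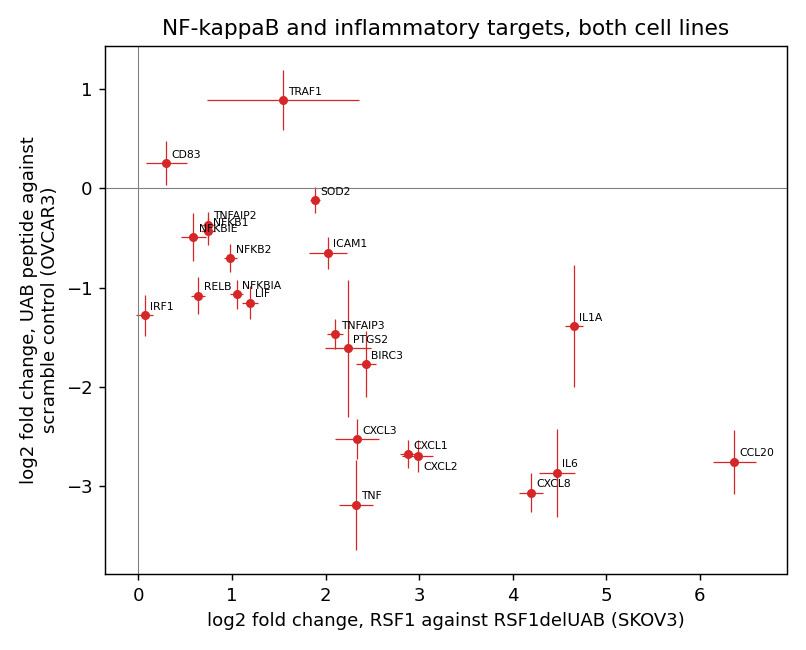
Log2 fold change of the 23 NF-kappaB and inflammatory targets tested in both lines, RSF1 against RSF1delUAB in SKOV3 (horizontal) and UAB peptide against scrambled peptide in OVCAR3 (vertical); points are genes, bars are standard errors, and grey lines mark 0. For 21 of the 23 genes the signs are opposite, with CXCL8 at 4.19 and -3.07.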

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

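The offsets per chromosome arm and per gene length, the crossed pairing, the overlap without 16p and the list tests without single replicates were chosen after seeing the data; the other alternatives were planned. Against a fold of 1.5, 3077 higher and 2278 lower genes passed for RSF1 against control, 3009 higher and 2179 lower for RSF1delUAB against control, 639 higher and 705 lower for RSF1 against RSF1delUAB and 266 higher and 289 lower in OVCAR3, and the RSF1 log2 fold change of 0.56 between constructs did not pass; this test asks for a larger change by construction. With upper-quartile scaling 6343 higher and 4889 lower, 6071 higher and 5039 lower, 3543 higher and 2970 lower and 1051 higher and 968 lower genes passed in the same order, and with the gene-length offset 6095 higher and 5309 lower, 6031 higher and 5344 lower and 3552 higher and 3325 lower in the SKOV3 comparisons, so which direction held more genes in RSF1 against RSF1delUAB turned with both, as with the arm offset (3166 higher and 3036 lower). With an estimated correlation 2, 2, 8 and 0 lists passed in the same order, and with fry, which asks another question, 24, 26, 20 and 0. With the arm offset 7 named genes changed sign: HMGXB4 (-0.38), SMARCA5 (0.10), DLGAP5 (-0.00459), RPL15 (0.0299) and ATP5F1B (0.0346) in RSF1 against control, and MSMO1 (0.0306) and PES1 (-0.29) in RSF1delUAB against control; the offset removes arm medians by construction. With it 7, 7, 3 and 8 named genes lost their call, and 8615 of 11261, 8676 of 11150, 5542 of 6468 and 1706 of 2004 genes kept call and direction. Across genes with a log2 CPM of at least 4 the correlation of both constructs was 0.889, and without single controls 0.858 to 0.861; the cause was not tested.

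Leaving out single replicates gave 5522 to 5900 higher and 5152 to 5733 lower genes for RSF1 against control, 5445 to 5525 and 5010 to 5073 for RSF1delUAB against control, 2577 to 3374 and 2848 to 3707 for RSF1 against RSF1delUAB, and 633 to 1194 and 707 to 1045 in OVCAR3, lowest without control replicate 1. The set higher in RSF1 than RSF1delUAB had OVCAR3 medians of -0.0934 to -0.0259, and -0.136 for members changed at least 2-fold; the cause was not tested. DESeq2 kept direction and call for 132 of 132, 132 of 132, 114 of 114 and 82 of 86 named genes. In OVCAR3, 25 of 86 named genes lost their call at least once, against 0 of 132, 0 of 132 and 4 of 114 in the SKOV3 comparisons. Replicate numbers did not pair the libraries over all groups (same-number correlations -0.201 to 0.259 in SKOV3 and -0.516 in OVCAR3). Between RSF1 and RSF1delUAB same-number correlations were 0.240, 0.259 and 0.0343, and those of different numbers -0.286 to 0.0337. A pairing of these 2 groups is thus not excluded. The negative correlation in OVCAR3 led to a crossed pairing: with control 1 paired to UAB 2 and control 2 to UAB 1 in OVCAR3, 2560 genes were higher and 2537 lower. This pairing was picked from the deviations of the same libraries, and no label gives it. A smaller residual spread and more calls are thus built in, and these counts do not speak for a pairing. With the replicate number as a block the counts were 5668 higher and 5496 lower, 5687 higher and 5320 lower, 3012 higher and 3321 lower and 928 higher and 842 lower. Direction and call were kept by 132 of 132, 132 of 132 and 114 of 114 named genes in SKOV3, but by 74 of 86 in OVCAR3. With 2 libraries per group and 2 residual degrees of freedom, the OVCAR3 fit recovered 17.9% of simulated 1.5-fold changes. The simulation changed 200 of 17662 genes, whereas 2004 of 18359 were called in the data. A call in the simulation therefore needed a smaller unadjusted p, and its recovery does not carry over to the data. Small changes in OVCAR3 can still be missed.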

Other observations

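For the chromosome arms the tests of GC content and length and of an effect that does not need the UAB region, and for ERBB2 the test of the gene alone, were chosen only after the result was seen, and the gene set of the GC test around ERBB2 was widened after its value was seen. Among the 262 genes called higher with RSF1 and lower with the peptide, the first 5 by size of change in the line that changed less were looked up after their values were seen. The acute-phase gene SAA1 differed by 3.92 between RSF1 and RSF1delUAB in SKOV3 and by -4.42 with the UAB peptide in OVCAR3, and its paralog SAA2 by 3.66 and -3.90. The chemokine CXCL8 was at 4.19 and -3.07, the cytokine IL6 at 4.47 and -2.87, and the muscle gene IGFN1 at 2.86 and -2.95.

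Of collagens and integrins, 18 rose and 12 fell of 30 in RSF1 against control, and the list did not pass (adjusted p = 0.477). Among its members that the naming rule takes, the hemidesmosome genes ITGB4 and COL17A1 had log2 fold changes of -5.26 and -4.22, while the integrin ITGB3 stood at 4.21.

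Whole chromosome arms differed between control and both construct groups. After trends with GC content and gene length were removed, the SD of arm medians was 0.351 against 0.379 before, which argues against those trends as the whole cause. A difference in copy number between the control cells and the construct cells may account for it: more and less expressed genes gave the same arm shifts (r 0.955 over 40 arms), although any arm-wide shift would. An effect of both constructs that does not need the UAB region cannot be told apart from it, since both are compared with the same controls (r 0.964). No DNA measurement was analysed here.

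Around ERBB2, 97.7% of 44 neighbours were lower with RSF1 than with RSF1delUAB, which argues against a change of ERBB2 alone. Their median after GC and length trends were removed was -0.613, against -0.64 before. A copy number of the segment that differs between the construct groups could give this pattern, with a highest median of -0.570 over the 9 pairs of libraries; against control the median was -0.23 with RSF1 and 0.50 with RSF1delUAB, so a loss in the cells given RSF1 alone does not account for the whole gap. Any change of the whole segment, and an effect of the UAB region, stay open.

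The NF-kappaB list differed in both lines. In RSF1 against RSF1delUAB its median was 2.06 before, 2.08 with the length offset and 2.06 with the arm offset, and in OVCAR3 it was -1.39, -1.37 and -1.45 in the same order. Neither trend therefore accounts for the whole pattern. One hypothesis is that the UAB region of RSF1 raises these genes, since levels were lower with RSF1delUAB than with RSF1 in SKOV3. The peptide is of the UAB region itself, so lower levels with it in OVCAR3 do not follow without a further step, which was not tested. With RSF1delUAB the list also lay below the control vector, which the hypothesis does not account for. The hypothesis was found and tested on the same data. No test here separates it from other differences between the cell populations. The OVCAR3 list call did not hold with an estimated correlation (adjusted p = 0.305). Both constructs at matched levels in separate cultures, and the peptide given to the SKOV3 cells with RSF1, would test the hypothesis.

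In each SKOV3 comparison, 3 against 3 libraries make 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes. The real splits gave 11261, 11150 and 6468 genes and the highest of the others 0 in each by edgeR, with up to 353, 156 and 949 genes at an unadjusted p under 0.05.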
